A study of Homo sapiens with 7 samples.

How the data were processed

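Guide RNA representation was measured by amplicon sequencing of genomic DNA from C4-2B cells, a human prostate cancer line derived from LNCaP cells that grows independently of androgen and metastasises to bone in mice. The cells were CRISPRi-ready, meaning that they carry a catalytically dead Cas9 repressor that silences the site a guide RNA (sgRNA) directs it to without cutting the DNA. The cells received a focused library of guides against selected sites together with non-targeting guides, per the labels. The labels give 7 libraries. Of these, 6 came from subcutaneous xenograft tumours in mice at the end of the screen and 1 from cells kept in culture for about 10 doublings. The tumour titles carry a number from 1 to 3 and the letter L or R, whose meaning the labels do not give.

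A single table was analysed. It holds the result of a fit made by the authors for each guide and 0 columns of values per library, so the depth of each library is unknown and no replicate error between tumours could be computed. UMI-tools, cutadapt, Bowtie2 and SAMtools are named, with build hg38, per the submitters' processing notes, without versions or order. The counting, the logistic fit, the libraries it set against each other and the way tumours were combined are not given in the sources used here. The table's 6 measurement columns were read as follows. The estimate is the deposited logistic coefficient and was taken as a natural log of an odds ratio, the usual scale of such a fit; the file does not name the base. The deposited logit.z score equals the estimate over its standard error, and the standard error was recovered from that ratio. Odds ratios and their intervals below were computed here from the deposited estimate and that standard error. The deposited logit.p is the 2-sided normal p-value of that score, with 0 guides off by more than 1e-12. The deposited rescaled z score is a straight-line function of logit.z with 1 shift (0.0404) and 1 scale (1.35) for every guide, again with 0 guides off by more than 1e-12. Those constants are not the mean (-0.83) and SD (1.47) of logit.z in the table. What set them, other guides or some other choice, is not stated in the file. The deposited pv p-value is the 2-sided normal p of the rescaled score, and the deposited q-value is its Benjamini-Hochberg adjustment over the 466 guides of the table. The sign is not defined in the file either. Its name speaks of enrichment, and the study's description speaks of guides recovered from tumours, so a negative value likely stands for a guide less represented in the tumours than in the comparator. "Lower" and "higher" below refer to the sign of the deposited values.

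A guide's name gives a region number, a chromosome and a guide number, for all guides of the table. Coordinates, target genes and guide sequences are not used here, and no gene was assigned to any region. The gene lists fixed in advance (androgen receptor axis, tumour suppressors, growth and survival genes, common essential genes, and a few single genes and elements) therefore could not be applied. Non-targeting guides are not analysed here, since 0 of the 466 guides carry a name other than that of a numbered region. The tests planned against non-targeting guides were replaced as follows. Each region with at least 2 guides was compared with sets of the same number of guides drawn at random from the table (100000 draws, 2-sided, Benjamini-Hochberg over 94 regions), which had been listed as the alternative background before the data were examined. The second comparison was added after the data were seen. It combined the rescaled scores of a region as their sum over the square root of their number and took the reference to have mean 0 and SD 1 on the authors' scale, with guides independent of each other. Agreement between guides of a region was measured by the one-way intraclass correlation, with 10000 reassignments of guides to regions and a bootstrap over regions for the 95% interval. The shift of all regions from 0 was tested by flipping the signs of region means at random (100000 flips). The repeat measurements in these tests are guides of one region, not tumours, so their p-values leave out the spread between animals.

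The region tests were tested on simulated data with the real arrangement of 94 regions, 50 simulated screens per size and 10 regions changed. A shift of -1 on the authors' scale was recovered in 8.0% of changed regions against random guides and 15.2% on the authors' scale, a shift of -2 in 71.8% and 95.8%, and a shift of -3 in 98.0% and 100%. With no region changed, the mean number of false calls was 0.04 and 0.02. The simulated scores had mean 0 and SD 1, whereas the rescaled scores of the table had mean -0.65 and SD 1.09. The false calls on the authors' scale therefore do not cover a shift common to all guides. The intraclass correlation passed its test in 84% of screens with the shift of -1 in 10 regions. Every guide of a changed region was shifted by the same amount. These rates therefore do not cover regions in which only some guides act.

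The text names the regions past an adjusted p of 0.05 in either region test and, where fewer than 5 passed against random guides, the 5 most extreme in each direction. It names the 5 lowest and 5 highest guides among those past the authors' adjusted p of 0.05. This rule for names was fixed before the data were examined, except that calls on the authors' scale were included afterwards. Alternatives covered the threshold, the centring, the statistic for a region, the minimum number of guides, their weights and the removal of extreme guides. Refits per library, another count model, other filters and leaving out single tumours need values per library and were not run. Calculations used Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3, and plots used Matplotlib 3.10.9.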

Results

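The screen asked which of a set of selected non-coding sites, when silenced, altered the representation of C4-2B prostate cancer cells in xenograft tumours. The table held 466 guides against 95 numbered regions on 19 chromosomes. Of these regions, 89 had 5 guides, 5 had 4 and 1 had a single guide. Chromosome 19 held 11 regions, chromosome 16 held 10 and chromosome 3 held 9. Guide numbers ran from 1 to 470, and 4 of those numbers were not in the table. The median standard error of a guide's estimate in the authors' deposited table was 0.176 on the natural log scale, so that the 95% interval of a typical guide reached 1.41-fold either way. After the authors' rescaling, which widens the error 1.35 times, it reached 1.59-fold. Which libraries the fit compared and how it combined the tumours are unknown. The intervals and the authors' p-values may therefore leave out spread between tumours and between cultures, of which the labels give a single library.

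Single guides were compared first, to find sites whose silencing changed the abundance of cells carrying the guide. In the authors' deposited table, 6 guides were lower and 0 were higher at an adjusted p of 0.05. The lowest was guide 156 in region 151 on chromosome 22 (151_chr22_seq156). From the estimate in the authors' deposited table, its odds ratio was 0.214, with a 95% interval of 0.125 to 0.369. That interval, like those that follow, used the standard error after the authors' rescaling. Guide 246 of region 222 on chromosome 6 (222_chr6_seq246) had an odds ratio of 0.30 (0.164 to 0.547) from its estimate in the authors' deposited table. Guide 432 of region 902 on chromosome 3 (902_chr3_seq432) stood at 0.356 (0.203 to 0.624) from its estimate in the authors' deposited table. Guide 36 of region 1136 on chromosome 17 (1136_chr17_seq36) stood at 0.374 (0.237 to 0.589) from its estimate in the authors' deposited table. In the same way, guide 278 of region 296 on chromosome 19 (296_chr19_seq278) stood at 0.381 (0.221 to 0.655). The sixth, guide 310 of region 397 on chromosome 20 (397_chr20_seq310), lay outside the rule for names and was added after its value was seen. Its odds ratio from the estimate in the authors' deposited table was 0.458 (0.294 to 0.713). The adjusted p-values in the authors' deposited table were 1.02e-05 for 151_chr22_seq156, 0.0046 for 1136_chr17_seq36, 0.012 for 222_chr6_seq246, 0.032 for 902_chr3_seq432 and 0.038 for both 296_chr19_seq278 and 397_chr20_seq310. Each of the 6 guides came from a different region.

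No guide was higher past the threshold. At an unadjusted p of 0.05, the authors' deposited table held 61 lower and 3 higher guides, where 11.65 per direction would arise with no change. That expectation takes scores with mean 0 and SD 1, whereas the rescaled scores had mean -0.65 and SD 1.09. The imbalance therefore also reflects the shift of guides as a whole, described below. The highest score, chosen after the values were seen, belonged to guide 218 of region 1756 on chromosome 16 (1756_chr16_seq218). Its odds ratio from the deposited estimate was 2.27 (1.30 to 3.95), and its adjusted p in the authors' deposited table was 0.165. The largest estimate, also chosen afterwards, was that of guide 350 of region 511 on chromosome 14 (511_chr14_seq350). Its odds ratio from the estimate in the authors' deposited table was 6.44, but its interval ran from 0.963 to 43.0, which holds 1. The adjusted p of this guide in the authors' deposited table was 0.402.

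The count of called guides changed with both the zero and the width of the scale. With scores centred on the median of all guides, 151_chr22_seq156 alone stayed past the threshold (adjusted p = 3.56e-04), and with the authors' unscaled p-values, which leave out the 1.35-fold wider error, 47 guides were lower and 3 higher.

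**Figure D1:**
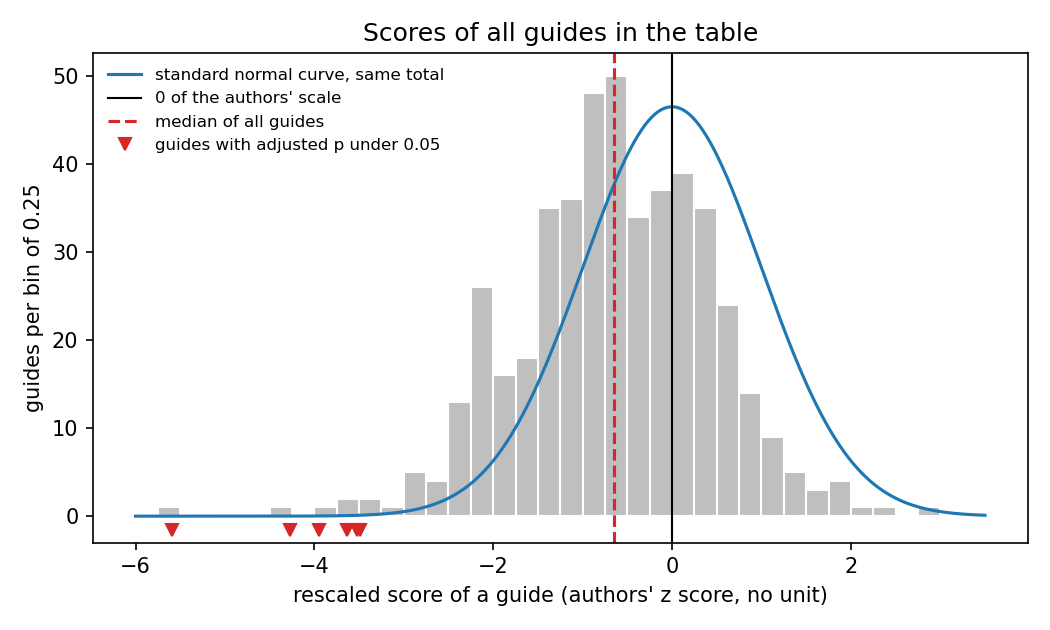
Histogram of the rescaled scores (horizontal axis, no unit) of the 466 guides, with the number of guides per bin of 0.25 on the vertical axis, the standard normal curve of the same total, a solid line at 0 and a dashed line at the median of -0.65. Triangles mark the 6 guides with an adjusted p under 0.05, all at scores of -3.49 or lower.

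Guides against the regions as a whole were lower than the zero of the authors' scale. Of the 466 guides, 330 (70.8%, 95% Wilson interval 66.5 to 74.8%) had a rescaled score below 0 and 136 above. The median odds ratio from the estimates in the authors' deposited table was 0.857, with quartiles of 0.733 and 1.04. Of the 95 regions, 86 had a mean score below 0 and 9 above. The mean of the region means was -0.64 ± 0.50 (SD over 95 regions), with a 95% bootstrap interval of -0.74 to -0.54. In a 2-sided sign-flip permutation test over regions, p was 1e-05, the smallest that 100000 flips can give. Leaving out the regions that hold a called guide gave a mean of -0.59. The non-targeting guides of the library were not analysed here, so this shift is relative to a zero whose origin is unknown.

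Regions were then compared, since 4 or 5 guides against one region are repeat measurements of it. On the authors' scale, 10 of 94 regions with at least 2 guides were lower and 0 were higher past an adjusted p of 0.05. The lowest was region 151 on chromosome 22 (151_chr22), with a mean score of -1.92 ± 2.34 (SD over its 5 guides) and an adjusted p of 0.0017 by the combined normal score over all 94 regions. Its guides ranged from -5.60 to 0.33, and without the lowest guide its mean was -1.0. Region 222 on chromosome 6 (222_chr6) had a mean of -1.79 ± 2.21, with 4 guides between -3.95 and -1.84 and the remaining guide at 1.86. Region 397 on chromosome 20 (397_chr20) had a mean of -1.63 ± 1.59, with guides 307 and 310 at -3.09 and -3.49. Region 1772 on chromosome 12 (1772_chr12) had a mean of -1.52 ± 0.94 and region 288 on chromosome 1 (288_chr1) a mean of -1.49 ± 1.13. Region 1193 on chromosome 16 (1193_chr16) had a mean of -1.44 ± 0.88 and region 1762 on the same chromosome (1762_chr16) a mean of -1.36 ± 0.86. The mean of region 296 on chromosome 19 (296_chr19) was -1.44 ± 1.45. That of region 1090 on chromosome 11 (1090_chr11) was -1.36 ± 0.51, and that of region 528 on chromosome 8 (528_chr8) was -1.28 ± 1.49.

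Among these 10 regions, the odds ratio of the mean estimate ranged from 0.614 for 222_chr6 to 0.738 for 296_chr19. In 5 of them (1772_chr12, 288_chr1, 1193_chr16, 1762_chr16 and 1090_chr11) every guide lay below 0. Whichever single guide was left out, 8 of the 10 kept an unadjusted p under 0.05 by the combined normal score. Without their lowest guide, 296_chr19 had 0.067 and 528_chr8 had 0.12 by that score. The 10 regions had been chosen by the same scores. With all guides, 34 of the 94 regions were lower at that unadjusted threshold, so this is a weak check. The tightest was 1090_chr11, whose 5 guides lay between -2.02 and -0.65 although none passed the threshold alone. The regions that held a called guide were 4 (151_chr22, 222_chr6, 296_chr19 and 397_chr20). Regions 902_chr3 and 1136_chr17, which also held a called guide, had mean scores of -1.0 ± 1.77 and -1.07 ± 1.91 and adjusted p-values of 0.10 and 0.091 by the combined normal score. In 902_chr3 only 2 of 5 guides lay below 0.

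No region passed the comparison with random sets of guides drawn from the same table. Against 100000 random sets, 0 of 94 regions were lower and 0 were higher after Benjamini-Hochberg adjustment in this permutation test. At an unadjusted p of 0.05, 3 regions were lower and 1 was higher, where 4.7 would arise by chance. The lower regions were 151_chr22 (permutation p = 0.011, adjusted 0.53), 222_chr6 (permutation p = 0.021, adjusted 0.66) and 397_chr20 (permutation p = 0.045, adjusted 0.87). The higher region, 795_chr19, had the smallest p of the 94 (permutation p = 0.0022, adjusted 0.20). The 10 calls on the authors' scale became 0 when scores were centred on the median of all guides. With guides reassigned to regions at random, the region mean at rank 10 from the lowest had a median of -1.27, against -1.28 observed. About as many regions with means that low thus arose without any difference between regions. Without the most extreme guide of every region, and of every set of reference values it was compared with, 0 of the 10 passed. Their means then lay between -1.25 in 222_chr6 and -0.77 in 528_chr8, all still below 0, and their adjusted p-values in this simulated reference test ranged from 0.061 to 0.21.

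The highest regions did not pass either test. Region 795 on chromosome 19 (795_chr19) had a mean of 0.91 ± 0.89, with each of its 5 guides above 0, between 0.06 and 2.40. Its odds ratio was 1.28, and its adjusted p was 0.20 in the permutation test against random guides and 0.12 by the combined normal score. After centring on the median of all guides, 795_chr19 passed the combined normal score as a higher region (adjusted p = 0.044), which the permutation test against random guides did not call. The other high regions were 172_chr3 with a mean score of 0.26 ± 1.41, 1756_chr16 with 0.25 ± 1.49, 1692_chr8 with 0.20 ± 0.86 and 414_chr8 with 0.11 ± 0.81. Each of these 4 had a mean below 0 without its highest guide, from -0.11 in 172_chr3 to -0.40 in 1756_chr16.

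**Figure D2:**
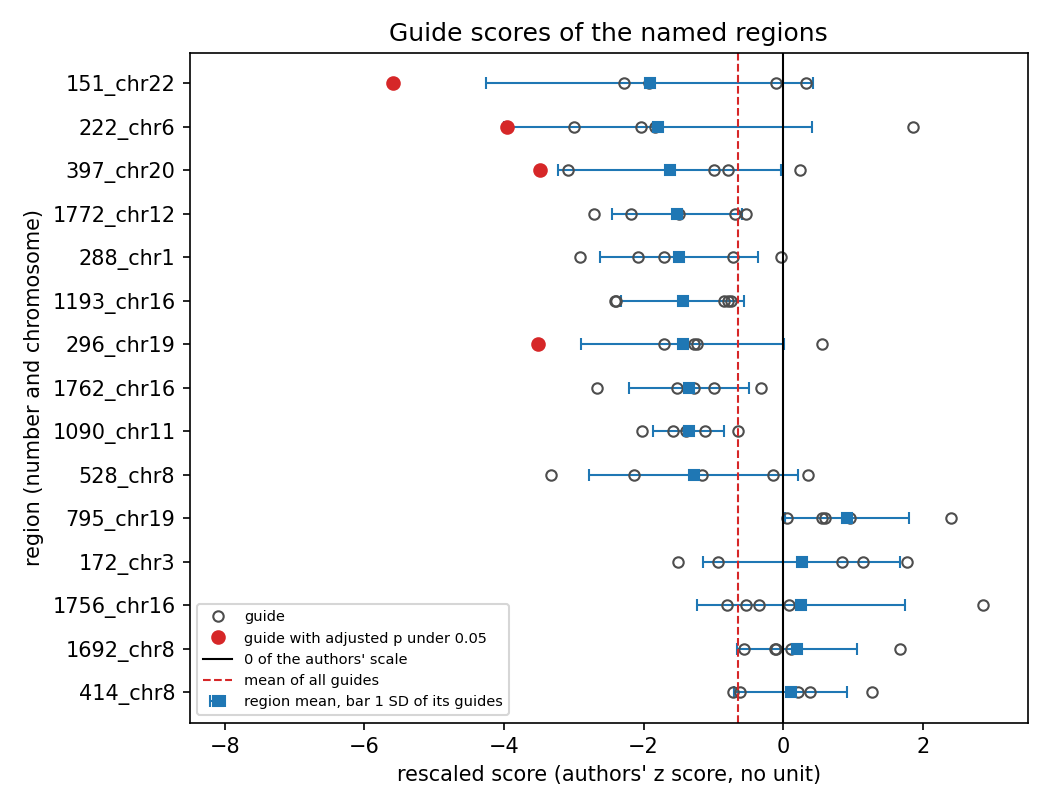
Rescaled scores (horizontal axis, no unit) of the guides of the 10 lower and 5 highest regions (vertical axis), with squares and bars for the mean and 1 SD over 5 guides, filled circles for guides with an adjusted p under 0.05, a solid line at 0 and a dashed line at the mean of all guides (-0.65). The 5 guides of 1090_chr11 lie between -2.02 and -0.65, whereas those of 151_chr22 spread from -5.60 to 0.33.

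Guides against one region were not measurably more alike than guides against different regions. The intraclass correlation of scores within the 94 regions was 0.0052 (95% bootstrap interval -0.053 to 0.066; 1-sided permutation p = 0.43). Scores varied within regions with an SD of 1.09. The means of regions with 5 guides had an SD of 0.501, and reassigning guides to regions at random gave 0.488 (95% of reassignments between 0.424 and 0.554). All 5 guides lay below 0 in 13 of the 89 regions with 5 guides, and reassignment gave a mean of 15.9 such regions (95% between 11 and 21). The upper limit of the interval corresponds to 6.6% of the variance in guide scores lying between regions, taken over all 94 regions. It limits neither the effect of a single region nor a shift common to all regions.

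**Figure D3:**
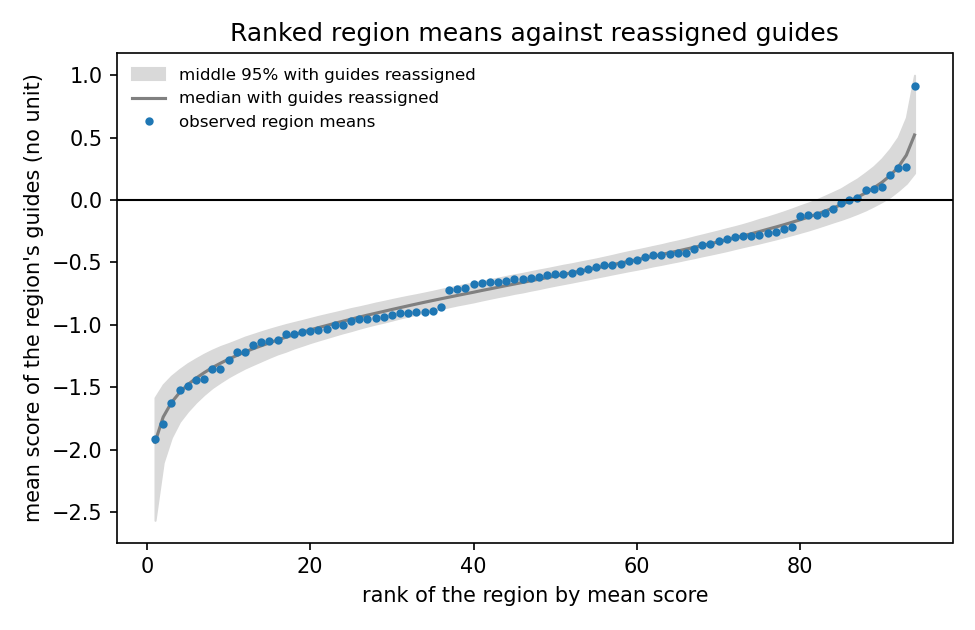
Mean rescaled score of each of the 94 regions with at least 2 guides (vertical axis, no unit) in order of rank (horizontal axis), with a line and band for the median and the middle 95% of 10000 reassignments of guides to regions. Of the 94 observed means, 93 lie inside the band for their rank.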

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

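The intraclass correlation over all guides was planned before the data were examined. The other tests in this part were added after the data were seen; for 2 of them, the intraclass correlation among the better measured guides and the number of regions with a guide that stands apart, the expected outcome was written down before the result was computed.

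A single guide of the named regions stood apart from the others of its region by Dixon's criterion, with guides taken as the repeat measurements. Guide 1756_chr16_seq218 scored 2.86, whereas the other 4 guides of region 1756 on chromosome 16 lay between -0.80 and 0.09. Chance gives about 1 such region in 20, and 2 of the 94 regions with 4 or 5 guides held one.

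The first pattern is that guides as a whole lay below 0. Poorly measured guides do not account for it, because the 233 guides with the smaller standard errors had a median score of -0.64 (95% bootstrap interval -0.72 to -0.41). A few strongly lower regions do not account for it either, because the median of the region means was -0.62 (-0.71 to -0.52). The reference behind the authors' scale stays open. The rescaling puts its zero at 0.0404 in logit.z, against a mean of -0.83 for the guides of the table. No reference guide was analysed here that would show whether such guides differ from these for a reason other than silencing. An effect of the silenced regions on growth also stays open as a hypothesis, since an intraclass correlation of 0.0052 (-0.053 to 0.066) neither shows nor excludes effects that are similar across most regions.

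The second pattern is that guides of one region were not alike. Random error of single guides is a candidate explanation: scores varied within regions with an SD of 1.09 (1.01 to 1.18), close to the SD of 1 that the reference would have if the authors' scale was set on it. Among the 233 better measured guides the intraclass correlation was -0.12 (-0.23 to 0.0072, 1-sided permutation p = 0.96 over 77 regions). By the outcome written down beforehand, this spoke against poorly measured guides as the explanation. It cannot decide the question, because a score is already divided by its guide's standard error. Guides with small and large standard errors therefore carry similar error on this scale. That a single active guide per region carries the effect cannot be told apart from chance: 2 regions held a guide that stood apart, where reassigned guides gave a median of 5. By the outcome written down beforehand, a count at or below that median spoke against this explanation. The test as run also required the count to lie beyond its counting error, and so left the explanation undecided. Both stood above the others of their region (1756_chr16_seq218 and, at 0.97, 92_chr14_seq448) and 0 stood below, but the count is too small to lie beyond its counting error, and the low guides 1136_chr17_seq36 (-4.27) and 151_chr22_seq156 (-5.60) missed the criterion of 0.71 with gaps of 0.62 and 0.56 of their region's range.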

How the results depend on the processing

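Counts of calls changed with the scale, the threshold and the statistic. Against the main 6 lower guides, an adjusted p under 0.01 gave 2, Bonferroni correction 3, centring on the median of all guides 1 and the unscaled p-values 47; higher guides numbered 0 under all of these except the unscaled p-values, which gave 3. An adjusted p under 0.10 gave 7 lower guides. On the authors' scale, the 10 lower regions became 4 with the median of the guides (3 of them among the 10), 0 without the most extreme guide of each region (means -1.25 to -0.77, smallest adjusted p 0.061) and 0 after centring on the median of all guides, which gave 1 higher region (795_chr19). Weighting by standard errors kept all 10, the top 3 guides per region gave 7 and a minimum of 5 guides gave 12. Against random guides, 0 regions passed in either direction under each of the 6 alternatives. The overall shift stayed below 0 in the 4 alternatives, from -0.59 without regions that hold a called guide to -0.82 in units of logit.z. These 4 summarise the same deposited scores, and logit.z is a straight-line function of the rescaled score. They could hardly change the sign and say little about processing. The intraclass correlation stayed under its threshold without the top and bottom 1% of guides (-3.56e-05), on the estimates (-0.0015) and in the 233 better measured guides (-0.12). Centring was listed before the data were examined, and the tests on the authors' scale, the unscaled p-values, the variants of the overall shift and the intraclass correlations on the estimates and in the better measured guides were added after. No paired analysis was possible because the table has no values per library; for that reason the refits, normalizations, filters and pseudocounts, leaving out single tumours and other splits of the libraries were not run, nor were the tests against non-targeting guides. The depth of the libraries is unknown, and the cause of each difference was not tested beyond the construction of the alternative.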

Other observations

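The tests below were added after the data were seen. For neighbouring guide numbers the expected outcome was written down before the result was computed; the tests of chromosome, place, region number and noisy guides were chosen after their values were seen.

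By chromosome, among those with at least 3 regions, the lowest means of region means were those of chromosome 20 (-1.02 over 3 regions) and chromosome 6 (-0.99 over 4 regions), and the highest were those of chromosome 8 (-0.36 over 6 regions) and chromosome 2 (-0.38 over 6 regions). Chromosome accounted for 13.5% of the variance of region means, against a median of 18.7% when regions were permuted (permutation p = 0.84, adjusted p = 0.84 over 4 hypotheses). A difference between chromosomes was not detected, and 95 regions on 19 chromosomes leave small ones open.

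The order of the guides gave the lowest unadjusted p of the 4 hypotheses. In the 89 regions with 5 guides, the guide listed second had a mean score of -0.96 ± 1.17 (SD, n = 89 regions), and the means at the other places lay between -0.63 and -0.51. The largest distance of a place from the mean of all was 0.309. The variance of the 5 place means, tested by permutation within regions, gave p = 0.048 (adjusted p = 0.19), which did not pass after adjustment. If guides were listed by predicted strength, those at the first place might be expected to score lowest, but they averaged -0.63, and the order's meaning is not stated. Of the 6 called guides, 3 held the second place (151_chr22_seq156, 222_chr6_seq246 and 902_chr3_seq432). Their scores are part of the second-place mean above, so this count is no separate evidence.

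Consecutive guide numbers within a region differed by 0.0066 less in score than other pairs of the region (value -0.0066; 1-sided permutation p = 0.46, adjusted p = 0.84). The number of a region did not track its mean score over 95 regions, with Spearman's rho of 0.030 (permutation p = 0.78, adjusted p = 0.84) and Pearson's r of 0.054 (permutation p = 0.60); without the 2 regions farthest from the median number, r was 0.12. Among the 47 guides with the largest standard errors, 19 (40.4%) had an estimate above 0, compared with 122 of the other 419 (29.1%; Fisher's exact test, 2-sided p = 0.13, not among the 4 adjusted hypotheses).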
